A study of Homo sapiens with 48 samples.

How the data were processed

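RNA from 2 human breast cancer cell lines was measured on 48 Illumina HumanHT-12 bead arrays, 1 array per sample. Per the labels, total RNA was isolated with a column kit that included a DNase step, and biotin-labelled cRNA was made from it with an Ambion MessageAmp kit. Such kits prime on poly(A) tails, as general background. The arrays form 3 experiments: 24 arrays of MDA-MB-231 cells transfected with siRNA, 16 arrays of untransfected MDA-MB-231 cells followed over time, and 8 arrays of transfected EVSA-T cells. Groups were taken from the sample labels. The array identifiers place the samples on 4 slides of 12 arrays each.

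The deposited table of signals holds 1 value per probe and array. It is named as non-normalized, but its values run from 5.47 to 14.9, so these deposited values were read as log2 signals and raised to the power of 2 before further steps. The same table gives a detection p-value per probe and array, per the file headers, in steps of 1 in 770. Its method is not given in the sources used here, and it does not always rise as the deposited signal falls. The authors also deposited a series matrix in log2 units, in which every array has the same set of values, as quantile normalization over all 48 arrays gives. That matrix served as an alternative. The scanner software is not given in the sources used here.

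The table held 48107 probes, of which 3 were dropped for a missing value. Of the rest, 30112 had 1 gene symbol, 8 had several and 17984 had none. Only probes with 1 symbol entered the tests. Their symbols were matched to current ones by Entrez identifier, except for 39 genes that the reference did not hold, and 0 symbols changed. No genome build comes with the probes, so no coordinates are given. BIRC3, the gene of cIAP2, has no probe with its symbol.

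Each experiment was processed by itself in R 4.3.3 with limma 3.58.1. The neqc function corrected for background, with the mean and SD of the negative controls inferred from the detection p-values, added an offset of 16, and quantile normalized the arrays on the log2 scale. Probes were kept when the detection p was under 0.01 on at least as many arrays as the smallest group of that experiment holds, which is 3 in the siRNA experiment and 2 in the others. A gene detected only with BV6 can thus enter through its rise, which adds to the shares of list members called higher. The probe with the highest mean stood for its gene, which left 9586 genes in the siRNA experiment, 9944 in the kinetic and 8422 in EVSA-T. For the comparison of cell lines, the 12 siCtrl and siTNFR1 arrays of MDA-MB-231 and the 8 of EVSA-T were processed together, with 10716 genes. Replicate arrays correlated across genes at r of 0.981 or more, lowest between the BV6 3 h arrays, and no array was a copy of another. Arrays carry no count of molecules, so the number of arrays and the signal over background limit the precision. The median signal of undetected probes lay between 75.1 and 93.7 on the linear scale, so small changes of dim genes are compressed.

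Comparisons were fitted with limma, 1 coefficient per group and 1 shared spread per gene and experiment, with 16, 8, 4 and 12 residual degrees of freedom in the siRNA, kinetic, EVSA-T and joint fits. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the genes of a comparison, and an adjusted p under 0.05 was a call. Errors after ± are standard errors from these fits. Kinetic BV6 times were each compared with the mean of the untreated groups at 0, 9 and 15 h, so these 5 comparisons share their untreated arrays. Differences between responses were tested as interactions. Nothing in the labels says that replicates are separate cultures, so the p-values of these fits measure only the spread between samples, which may be technical.

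The replicate number in the sample labels could mark samples handled together. Residuals of arrays with the same number were therefore correlated across genes, and the numbers were taken to pair the samples where at least 3 pairs could be formed and each had r above 0.1. This held for BV6 in siCtrl cells (0.127 to 0.242), BV6 in siIRF1 cells (0.176 to 0.312), the kinetic at 6 h (0.150 to 0.293), 9 h (0.253 to 0.400), 12 h (0.253 to 0.332) and 15 h (0.153 to 0.293), and the EVSA-T interaction (0.162 to 0.379). With 2 replicates the deviations mirror each other, so these pairs are not all independent. Counts with the replicate number as a block stand beside those results where they differ by over 1.5 times.

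The choices were fixed before the data were examined, except where stated: comparisons, tests, 22 gene lists and the rule for naming genes. The lists cover NF-kB targets, the non-canonical NF-kB pathway, AP-1 family and immediate early genes, matrix metalloproteinases and the plasminogen system, chemokines and cytokines, the interferon response, interferon-gamma and IRF1 targets, antigen presentation by class I, the TNF receptor superfamily and its ligands, cell death and IAP genes, the integrated stress response, p53 targets, cell cycle, cholesterol synthesis, hypoxia and glycolysis, NRF2 and oxidative stress, the unfolded protein response and heat shock, luminal epithelial markers, mesenchymal and basal-like markers, leukocyte markers, fibroblast and endothelial markers, and control genes. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Lists overlap in members. The rule names the gene each siRNA targets, up to 10 of the largest rises and 10 of the largest falls among calls that were detected in each group and had non-overlapping replicates, up to 5 of the largest bounds among calls undetected in a whole group, up to 4 called members of each list, and a fixed panel of BV6, TNF and NF-kB genes. Non-overlap was not asked of interactions.

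Where a gene was not detected on any array of the dimmer group, its fold is given as a bound, "at least N-fold". The bound sets the mean of the brighter group against the dimmer group's mean, taken on each array as the higher of the lowest detected signal and the probe's own. Where the probe's own signal was the higher, the bound equals the fitted change, as for TRAF1 with BV6 in siCtrl cells. A bound allows for signal below detection and not for the spread between arrays, so the true fold may be smaller. The brighter group needed detection on at least 1 array only. No fold is given for a gene undetected on every array of both groups. Differences between responses are differences of fitted values, which are not exact where a gene was undetected in one of the groups, and medians of lists and classes include such fitted values.

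Early genes were those called higher at 3 h in the kinetic. Late genes were those not called at 3 h, called higher at 9 h and 15 h, and called higher at 9 h than at 3 h with BV6. Their differences of response in the transfected cells, which took no part in choosing them, were compared by 100000 permutations of the class labels. Overlaps between calls were tested with Fisher's exact test. The p-values of this test and of the permutations are taken over genes, which are not independent replicates, and measure no spread between samples. For comparisons that share control arrays, 100 simulated data sets of unchanged genes gave the correlation that sharing alone brings. Almost no gene is called in such data, so they cannot show how much sharing adds to overlaps between changed genes.

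The pipeline was tested on simulated data built from the arrays' spread. With 200 altered genes of 9586, the siCtrl comparison recovered 47.8% of 1.5-fold, 94% of 2-fold and 100% of 4-fold changes, with 6 false calls. The EVSA-T interaction recovered 4.48%, 34.3% and 97% of such changes. Of 20 unchanged lists, camera called 0. The simulated genes varied independently, so this does not test camera on lists whose members vary together.

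The alternatives were no detection filter, the authors' series matrix, no background correction, all 48 arrays normalized together, the mean over a gene's probes, only the groups of a comparison in the fit, the replicate number as a block, the slide as a block and each slide alone, each replicate left out in turn, limma's trend and robust options, a further demand of a 1.5-fold change, other untreated references in the kinetic, other definitions of the early and late classes, and fry in place of camera. After the data were seen, a normexp correction without control probes and an offset of 50, the early and late classes measured in EVSA-T, and the classes without small nuclear and nucleolar RNAs were added. Probes with no gene symbol were left out of the main tests and fitted by themselves.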

Results

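Gene expression was measured in MDA-MB-231 and EVSA-T, 2 established human breast cancer cell lines, after treatment with BV6. BV6 is a bivalent Smac mimetic, a compound that antagonizes the inhibitor of apoptosis (IAP) proteins and leads to the loss of cIAP1 and cIAP2. In the kinetic experiment, untransfected MDA-MB-231 cells were treated with 50 nM BV6 and collected after 3, 6, 9, 12 and 15 h, and untreated cells were collected at 0, 9 and 15 h, with 2 arrays per group. In the siRNA experiment, MDA-MB-231 cells were transfected for 36 h with 5 nM of a control siRNA (siCtrl) or of siRNA against TNFR1 (siTNFR1, gene TNFRSF1A), RELA (siRELA) or IRF1 (siIRF1), and were then left untreated or given 50 nM BV6 for 9 h, with 3 arrays in each of 8 groups. EVSA-T cells received siCtrl or siTNFR1 in the same way and 5 nM BV6 for 9 h, with 2 arrays in each of 4 groups. The number of probes detected per array ran from 10597 to 13072 in the siRNA experiment, from 10822 to 12452 in the kinetic and from 10167 to 11786 in EVSA-T. The arrays of the siRNA experiment lay on slides 1 and 2, with both treatments of each siRNA on each slide. On slide 3 were all untreated kinetic arrays, both BV6 3 h arrays and replicate 1 of the later times, and on slide 4 were replicate 2 of those times and all EVSA-T arrays.

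The kinetic asks which genes respond to BV6 first and which follow, the purpose that the series title states. At 3 h, genes of the NF-kB pathway were already higher (n = 2 arrays against 6 untreated). NFKBIA and NFKBIE, which encode IkB proteins that hold NF-kB in the cytoplasm, rose by 1.69 ± 0.20 and 1.69 ± 0.22 log2. NFKB2 (the p100 precursor) rose by 1.44 ± 0.13, RELB, its partner subunit, by 1.56 ± 0.16, and MAP3K14, the kinase NIK of the non-canonical pathway, by 1.69 ± 0.22. Among genes detected in both groups the largest rise was that of GADD45A, a stress-response gene, at 1.75 ± 0.20 log2 (adjusted p = 0.00065), and CYP1B1 (1.72), the chemokine gene CXCL8 (1.71) and EDN1 (1.70), which encodes endothelin, were close to it. BIRC2, the gene of cIAP1, rose by 1.03 ± 0.19 and the cytokine gene LIF by 1.02 ± 0.17. CXCL1 was not detected on any untreated array and was at least 3.34-fold higher, with only 1 BV6 array detecting it. MAFF, a small Maf transcription factor, rose by 1.18 ± 0.19, and 1 of its 2 other probes went the other way. Among 11 genes that fell, NDP, a Wnt-pathway ligand, fell by 1.36 ± 0.18 log2, ID1 by 1.15 ± 0.19, SPRY1, a feedback inhibitor of receptor signalling, by 0.95 ± 0.16 and SOX9 by 0.71 ± 0.13.

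In all, 38 genes were called at 3 h, 27 of them higher. The list of NF-kB targets had 8 of 36 measured members higher, or 16 when adjusted over the list alone, with a median of 0.40 log2 (adjusted p = 0.143 with an estimated correlation). In the list of AP-1 family and immediate early genes, 1 of 24 members rose, or 5 adjusted over the list alone, and camera's call (adjusted p = 0.00444) went to an adjusted p = 0.446 with an estimated correlation. FOS, an AP-1 subunit, was not detected on any array of either group at 3 h. The 3 h count rested on single arrays, with 390 calls without BV6 3 h replicate 1 and 15 without replicate 2.

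At 6 h the rises included TRAF1, an adaptor of TNF receptors, at 3.00 ± 0.24 log2, RNU4-2, the gene of the U4 small nuclear RNA, at 2.71 ± 0.33, and NFKBIE at 2.41 ± 0.22. NFKB2 rose by 2.10 ± 0.13, RELB by 1.93 ± 0.16, RRAD by 1.85 ± 0.23 and EGR1, an immediate early transcription factor, by 1.63 ± 0.23. TNFAIP3, which encodes A20, an inhibitor of NF-kB signalling, was at least 2.23-fold higher. CXCL2, detected on only 1 BV6 array, was at least 3.23-fold higher. SPRY1 fell by 1.07 ± 0.16 and PFKFB4, a regulator of glycolysis, by 1.29 ± 0.19. Calls numbered 47, with 41 higher, and 94 with the replicate number as a block. Of NF-kB targets 12 rose, or 23 adjusted over the list alone (median 0.68 log2, adjusted p = 0.018 with an estimated correlation). Without BV6 6 h replicate 1 there were 9 calls, and without replicate 2 there were 22.

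By 9 h more immediate early genes had joined. The list of AP-1 family and immediate early genes was already called up at 6 h by camera at the preset correlation (median 0.30 log2). FOS, undetected on every untreated array, was at least 9.07-fold higher, FOSB at least 3.49-fold and CXCL2 at least 12.8-fold. EGR1 rose by 2.90 ± 0.23 log2, ATF3, a stress-induced transcription factor, by 2.10 ± 0.35, IL6 by 2.05 ± 0.29 and JUN by 0.92 ± 0.16. NFKB2 stood at 2.53 ± 0.13 and TRAF1 at 2.55 ± 0.24, while RNU4-2 had risen by 4.79 ± 0.33 and RN7SK, the 7SK RNA that holds back transcription elongation, by 2.47 ± 0.17. NREP fell by 1.39 ± 0.22 and the hypoxia-responsive gene NDRG1 by 0.83 ± 0.15. AP-1 family and immediate early genes had 10 of 24 members higher, or 13 adjusted over the list alone (median 0.48 log2, adjusted p = 0.011 with an estimated correlation). Between 3 h and 9 h with BV6, 5 of them were called higher at 9 h, or 11 adjusted over the list alone, and camera's adjusted p was 6.02e-08, or 0.243 with an estimated correlation. Calls numbered 121, with 95 higher, and 219 with the replicate number as a block. Without BV6 9 h replicate 1 there were 30 calls and without replicate 2 there were 80, and against untreated cells of 9 h alone there were 54.

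The response kept widening at 12 h and 15 h. At 12 h, 252 genes were higher and 161 lower, and at 15 h 385 and 307. FOS was at least 19.8-fold higher at 12 h and at least 29-fold at 15 h, and FOSB at least 15.7-fold at 15 h. CXCL2 reached at least 28.1-fold, CXCL1 at least 20.4-fold and CCL20, a chemokine gene, at least 8.86-fold. EGR1 rose by 3.86 ± 0.23 log2, RRAD by 3.95 ± 0.23, ATF3 by 3.56 ± 0.35, CXCL8 by 3.08 ± 0.32, IL6 by 2.93 ± 0.29 and NFKBIA by 2.64 ± 0.20, while NFKB2 (2.55 ± 0.13) and RELB (1.86 ± 0.16) stayed near their 9 h values. TNF itself was at least 2.44-fold higher at 12 h (adjusted p = 0.0273) and at least 2.22-fold at 15 h (adjusted p = 0.0327), with 1 of 2 BV6 arrays detecting it. TNFSF10, the gene of the death ligand TRAIL, rose by 1.61 ± 0.37 and HMOX1 by 1.05 ± 0.18 at 15 h. Falls at 15 h included SNTB1 by 1.42 ± 0.25 log2, CTNNBIP1 by 1.34 ± 0.23, INHBB by 1.33 ± 0.18, and PHGDH and PSPH, enzymes of serine synthesis, by 1.18 ± 0.16 and 1.18 ± 0.21. Counts with the replicate number as a block were 673 at 12 h and 1112 at 15 h. Against untreated cells of 15 h alone there were 397 calls at 15 h. Without BV6 12 h replicate 1 there were 117 calls at 12 h, and without BV6 15 h replicate 1 or 2 there were 238 or 291 at 15 h.

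**Figure D1:**
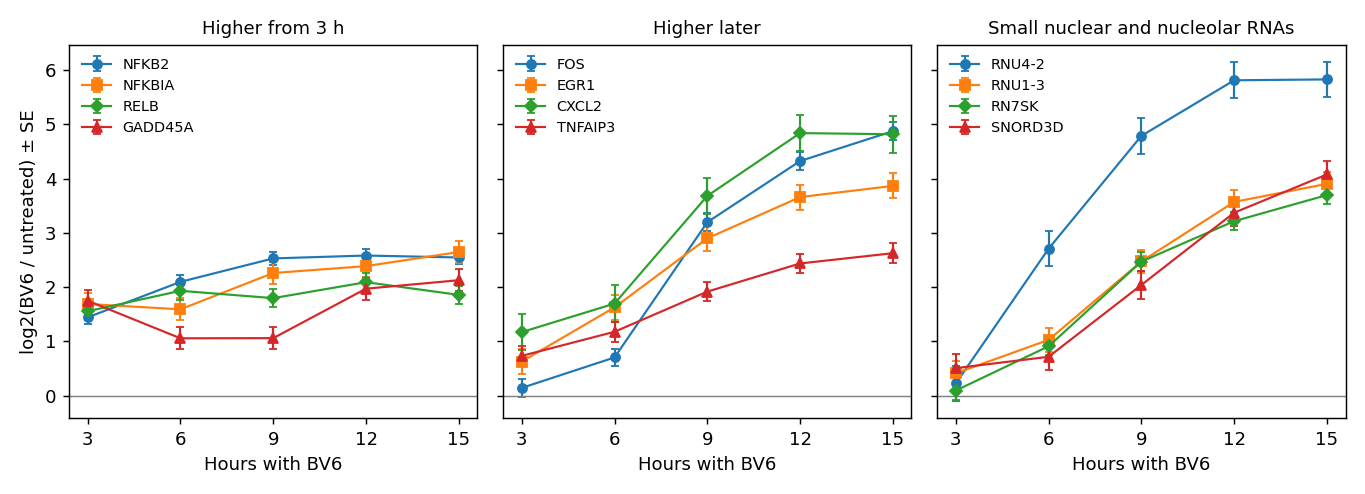
Change with BV6 against untreated MDA-MB-231 cells (log2, vertical axis) by hours of treatment (horizontal axis), as means of 2 arrays with bars of 1 standard error. NFKB2, NFKBIA, RELB and GADD45A stand between 1.44 and 1.75 at 3 h, while RNU4-2 reaches 5.83 at 15 h; points of genes undetected in untreated cells (FOS, CXCL2, TNFAIP3) are fitted values, for which the text gives bounds, and FOS at 3 and 6 h and TNFAIP3 at 3 h were detected on no array of either group.

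At 15 h, NF-kB targets had 27 of 36 members higher, or 32 adjusted over the list alone (median 1.31 log2), and on slide 3 alone the median was 1.54. AP-1 family and immediate early genes had 13 of 24 higher, or 17 adjusted over the list alone (median 0.74, and 0.82 on slide 3 alone), the non-canonical NF-kB pathway 5 of 14, or 8, and chemokines and cytokines 10 of 17, or 13. These lists had an adjusted p = 0.0103 with an estimated correlation. TNF receptor superfamily and ligand genes had 9 of 18 higher, among them TNFRSF10D (1.24 ± 0.16), a decoy receptor of TRAIL, or 11 adjusted over the list alone (adjusted p = 0.0464 with an estimated correlation). Cell cycle genes shifted down, with 2 of 37 called lower, MCM6 and KIF11, or 3 adjusted over the list alone (median -0.20, adjusted p = 0.00282, and 0.351 with an estimated correlation). Antigen presentation by class I had TAP1 (0.90 ± 0.15) and HLA-B (0.61 ± 0.13) higher, of 18 members (adjusted p = 0.0272, and 0.143 with an estimated correlation), and interferon-gamma and IRF1 targets had 3 of 18 higher (adjusted p = 0.0436, and 0.516 with an estimated correlation). For p53 targets, 3 of 16 were higher, CDKN1A and AEN among them (adjusted p = 0.0553), and with the replicate block the list passed at an adjusted p = 0.0420.

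The other lists did not pass at 15 h. Hypoxia and glycolysis genes had 1 of 23 higher (adjusted p = 0.586), after adjusted p-values of 0.015 at 9 h, with NDRG1 and PFKFB4 lower, and 0.00411 at 12 h, which were 0.287 and 0.159 with an estimated correlation. Luminal epithelial markers had 1 of 11 lower, ERBB3 (adjusted p = 0.158), after a call down at 12 h (adjusted p = 0.0331, and 0.298 with an estimated correlation). Mesenchymal and basal-like markers had 2 of 19 lower, SNAI2 (-0.78 ± 0.18) and CCN2 (-0.76 ± 0.15; adjusted p = 0.155). The integrated stress response had 3 of 21 higher and 1 lower (adjusted p = 0.994), with a median of -0.17 log2 although the test pointed up. Cholesterol synthesis had 1 of 15 lower (adjusted p = 0.483), NRF2 and oxidative stress genes 2 of 21 higher and 2 lower (0.586), the unfolded protein response and heat shock list 1 of 23 higher (0.158), cell death and IAP genes 2 of 27 higher (0.16), and the matrix metalloproteinase and plasminogen list 1 of 9 higher, PLAUR, and 1 lower, TIMP2 (0.83). Of 33 interferon response genes 0 were called at 15 h (adjusted p = 0.566), after calls of the list down at 9 h (adjusted p = 0.0248) and 12 h (adjusted p = 0.0446), which were 0.675 and 0.689 with an estimated correlation. Leukocyte markers (8 measured, adjusted p = 0.542), fibroblast and endothelial markers (4 measured, 0.586) and control genes (16 measured, 0.542) also had 0 calls.

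Time in culture without BV6 gave the background. Untreated cells at 15 h against 0 h had 0 calls with limma, and 290 genes at an unadjusted p under 0.05. NFKBIA differed by -0.01 ± 0.25 log2 there, and no list passed. Kinetic comparisons share the untreated arrays. Changes at 9 h and 15 h correlated across genes at r = 0.762, against 0.249 in simulations where only the controls are shared, and at 0.585 and 0.575 when each took its own 3 untreated arrays. For 3 h and 15 h, r was 0.216 against 0.248 simulated, and 0.175 and -0.00811 with separate controls, while the covariance exceeded the simulated one by 0.0148. Genes are not independent replicates in these correlations. Of 27 genes higher at 3 h, 15 were also higher at 15 h (1.05 expected if the comparisons were independent). When each time took its own untreated arrays, 16 and 15 genes were higher at both. Of 11 lower at 3 h, 1 was also lower at 15 h (0.340 expected, adjusted p = 0.318).

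In transfected cells given siCtrl, the effect of BV6 at 9 h was measured with 3 arrays against 3. TRAF1 was at least 10.2-fold higher, and CXCL2 (3.11 ± 0.24 log2), CXCL1 (2.74 ± 0.19), NFKB2 (2.62 ± 0.18) and NFKBIA (2.22 ± 0.19) were the largest rises among protein-coding genes detected in both groups. RNU4-2 rose by 4.21 ± 0.26, RN7SK by 3.56 ± 0.26 and RNU1-3, a gene of the U1 small nuclear RNA, by 3.32 ± 0.28. TNFSF10 rose by 1.90 ± 0.44, CXCL8 by 1.65 ± 0.26, IL6 by 1.55 ± 0.31, EGR1 by 1.55 ± 0.22 and GBP4, a guanylate-binding protein gene induced by interferon-gamma, by 1.47 ± 0.17. JUNB was at least 3.33-fold higher. FOS was called higher by 1.42 ± 0.21 log2, although its probe was detected on 0 BV6 arrays and 1 untreated array, and TNFAIP3 was called on arrays of which none detected it. RELA rose by 0.63 ± 0.17 (adjusted p = 0.0446), while IRF1 (0.51 ± 0.25, adjusted p = 0.332) and TNFRSF1A (-0.03 ± 0.18, adjusted p = 0.973) did not pass. PGCKA1 fell by 1.34 ± 0.17, NREP by 1.28 ± 0.18, SPRY1 by 0.97 ± 0.15 and the interferon-induced gene IFIT1 by 0.79 ± 0.15.

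With siCtrl, 244 genes were called, 167 higher and 77 lower, or 389 with the replicate number as a block. NF-kB targets had 19 of 29 members higher, or 24 adjusted over the list alone, with a median of 0.92 log2 (0.90 on slide 1 and 0.95 on slide 2; adjusted p = 1.84e-05 with an estimated correlation). AP-1 family and immediate early genes had 9 of 24 higher, or 16 higher and 1 lower adjusted over the list alone (median 0.56, with 0.54 and 0.39 on the slides; adjusted p = 3.98e-06 with an estimated correlation). Chemokines and cytokines had 7 of 13 higher, or 9 adjusted over the list alone, and the non-canonical pathway 6 of 14, or 6, among them MAP3K14 (0.93 ± 0.19) and BIRC2 (0.68 ± 0.16). Both had an adjusted p = 6.53e-05 with an estimated correlation. Among TNF receptor superfamily and ligand genes, the death receptor genes TNFRSF10A (1.13 ± 0.26) and TNFRSF10B (0.69 ± 0.13) and TNFRSF1B, the gene of TNFR2 (0.87 ± 0.14), were among 5 of 20 that rose (adjusted p = 0.0136 with an estimated correlation). Calls of interferon-gamma and IRF1 targets (2 of 16 higher, adjusted p = 0.0031), antigen presentation (1 of 18 higher, 0.0031) and cell cycle (1 of 38 higher, pointing down, 0.0379) were lost with an estimated correlation, at adjusted p-values of 0.145, 0.101 and 0.247. Interferon response genes had 1 of 33 higher, IFIH1, and 1 lower, IFIT1 (adjusted p = 0.0565). Without siCtrl BV6 replicate 1, 132 genes were called, and slides 1 and 2 alone gave 123 and 30.

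Genes called higher at 9 h in the untransfected cells were looked up in siCtrl cells, which had no part in choosing them. Of the 95, 90 were measured, 89 had the same sign and 69 were called (1.64 expected by chance, Fisher's exact test adjusted p = 4.80e-107), with a median of 0.99 log2. Of 26 genes lower, 25 had the same sign and 5 were called, with a median of -0.46.

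The siRNAs were compared with siCtrl in untreated cells to see what each knockdown does by itself. TNFRSF1A was not detected on any siTNFR1 array and was at least 18.5-fold lower, RELA was likewise undetected with siRELA and at least 3.47-fold lower, and IRF1 fell by 3.35 ± 0.25 log2 with siIRF1. With siTNFR1, PGM2, a phosphoglucomutase gene, fell by 1.92 ± 0.15, MIDN by 1.49 ± 0.20 and SOD2 by 0.60 ± 0.13. PTPMT1 rose by 1.69 ± 0.13, WSB1 by 1.61 ± 0.22, CIRBP, a cold-inducible RNA-binding protein gene, by 1.48 ± 0.11, and the glucose transporter gene SLC2A3 by 1.40 ± 0.16. The count was 317, with 228 higher. Of the 21 lists tested there, hypoxia and glycolysis alone passed, with SLC2A3 and KDM3A of 24 members higher, or 4 adjusted over the list alone (adjusted p = 0.016, and 0.218 with an estimated correlation). PTPMT1, WSB1, CIRBP, SLC2A3 and KDM3A were higher with each of the 3 siRNAs. In untreated siCtrl cells, on arrays that also served to call these genes, WSB1 (-2.00 log2), PTPMT1 (-1.87), CIRBP (-1.66), SLC2A3 (-0.63) and KDM3A (-0.27) lay below untransfected cells. CXCL1 was called lower with each of the 3, but it was detected on only 1 untreated siCtrl array, so the size of its fall was not measured. Without siTNFR1 untreated replicate 1 the count was 193, without siCtrl untreated replicate 3 it was 198, and with the slide as a block it was 487.

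With siRELA, 2012 genes were called, 949 lower. CXCL8 fell by 3.34 ± 0.26 log2, the RNA export gene THOC1 by 2.83 ± 0.13, the chaperone gene HSPA5 by 2.13 ± 0.28 and IL32 by 1.79 ± 0.22. The mitotic regulator CDC20 was lower too (-2.57 ± 0.13), and IL6 was at least 6.28-fold lower. NF-kB targets had 11 of 29 members lower, among them CD83 (-1.49 ± 0.14), NFKBIA (-1.10 ± 0.19) and SOD2 (-0.99 ± 0.13), or 11 adjusted over the list alone (median -0.31 log2, with -0.33 on slide 1 and -0.18 on slide 2; adjusted p = 5.48e-07, and 0.116 with an estimated correlation). Chemokines and cytokines had 5 of 13 lower (median -0.32, with -0.41 and -0.77 on the slides; adjusted p = 0.000111, and 0.0975 with an estimated correlation), the integrated stress response 7 of 19 lower (0.0369, and 0.305) and cell cycle 9 of 38 lower and 1 higher (0.002, and 0.125). Hypoxia and glycolysis had 5 of 24 higher and 1 lower (adjusted p = 0.0264, and 0.233 with an estimated correlation). WSB1 rose by 2.18 ± 0.22, SLC2A3 by 2.17 ± 0.16 and the adaptor gene GRB10 by 2.10 ± 0.23, but these and KDM3A rose with all 3 siRNAs. For them untreated siCtrl cells, on arrays that also served to call them, lay below untransfected cells. The values were -2.00 log2 for WSB1, -1.66 for GRB10, -0.63 for SLC2A3 and -0.27 for KDM3A. COL8A1 rose by 1.79 ± 0.24 and GCLM fell by 0.71 ± 0.14, but other probes of both went the other way. On slides 1 and 2 alone the counts were 1132 and 536.

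With siIRF1, 2087 genes were called, 1193 lower, and most interferon response genes were among them. Of 33 measured, 25 fell and 0 rose, or 27 lower adjusted over the list alone (median -0.85 log2, with -0.81 on slide 1 and -0.87 on slide 2; adjusted p = 0.000375 with an estimated correlation), among them HERC6 (-1.94 ± 0.19), IFI35 (-1.60 ± 0.15) and BST2 (-0.96 ± 0.11). Interferon-gamma and IRF1 targets had 11 of 16 lower, GBP1 (-1.67 ± 0.19) and HLA-DMA (-1.56 ± 0.17) among them (median -0.94, with -0.73 and -1.02 on the slides; adjusted p = 0.0108 with an estimated correlation), and antigen presentation 11 of 18 lower, or 13 adjusted over the list alone (median -0.71, adjusted p = 0.00287 with an estimated correlation). PSMB9, an immunoproteasome subunit, was at least 7.89-fold lower, PSMB10 fell by 1.56 ± 0.14 and PSMB8 by 1.18 ± 0.12. NF-kB targets (7 of 29 lower, 1 higher, adjusted p = 0.0174) and chemokines and cytokines (5 of 13 lower, 0.00702) lost their calls with an estimated correlation, at adjusted p-values of 0.374 and 0.154. PLAAT4 fell by 3.41 ± 0.36, STRADB by 2.90 ± 0.18 and the luminal transcription factor gene SPDEF by 2.44 ± 0.24, and KISS1 rose by 2.75 ± 0.41. Luminal markers KRT19 (-1.12 ± 0.15), CLDN7 (-1.06 ± 0.19), KRT7 (-0.50 ± 0.17) and KRT8 (-0.45 ± 0.13) fell, 4 of 11 in that list (adjusted p = 0.202, pointing down, although the list's median was 0.01), as did the macrophage-associated genes CD14 (-0.95 ± 0.19) and CD68 (-0.82 ± 0.13) in the leukocyte list, with 3 of 5 lower and 1 higher (adjusted p = 0.16). On slides 1 and 2 alone the counts were 790 and 785.

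These knockdown comparisons share the siCtrl arrays. The genes higher with siTNFR1 and siRELA overlapped in 177 cases (25.3 expected if independent), those of siTNFR1 and siIRF1 in 167 (21.3) and those of siRELA and siIRF1 in 276 (99.1), and the lower genes in 44 (8.81), 41 (11.1) and 220 (118). Simulations with shared controls and unchanged genes had a largest overlap of 0, but almost no gene is called in them. They therefore cannot show how much the shared controls add to these overlaps. Across genes the changes correlated at r = 0.476, 0.395 and 0.229 in the same order, where sharing alone gave 0.499 for each pair with siTNFR1 and 0.4997 for siRELA and siIRF1, and covariances exceeded the simulated ones by 0.0396, 0.0312 and 0.0267. The 3 untreated siCtrl arrays are too few to be split, but the BV6 arrays have siCtrl arrays of their own. There the 165 genes changed the same way by all 3 siRNAs had a median signed change of 0.769 log2, against 0.826 in untreated cells.

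The next question is how much of the BV6 response each knockdown removes. With siTNFR1, TRAF1 was still at least 8.12-fold higher with BV6, and CXCL1 rose by 2.22 ± 0.19 log2, NFKB2 by 1.8 ± 0.18, NFKBIE by 1.69 ± 0.16, GBP4 by 1.60 ± 0.17, CXCL8 by 1.56 ± 0.26 and RELB by 1.39 ± 0.19. RNU4-2 rose by 3.18 ± 0.26. JUNB was at least 1.75-fold and TNFAIP3 at least 1.64-fold higher, whereas FOS (adjusted p = 0.14, detected on 1 of the 6 arrays) and ATF3 (0.57 ± 0.15, adjusted p = 0.0618) did not pass. SOD2 was called higher, with its 1 other probe going the other way. NF-kB targets had 21 of 29 higher, or 23 adjusted over the list alone (median 0.86 log2, with 0.91 and 0.89 on the slides; adjusted p = 2.33e-05 with an estimated correlation), and AP-1 family and immediate early genes 2 of 24, or 6 adjusted over the list alone (median 0.20, with 0.28 and 0.18 on the slides; adjusted p = 0.000199 with an estimated correlation). NREP and TRERF1 each fell by 1.04 log2 (SE 0.18 and 0.19). In all 127 genes were called, 89 higher. Without siTNFR1 BV6 replicate 1 there were 82 calls, without siTNFR1 untreated replicate 3 there were 83, and the slides alone gave 16 and 45.

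The test of the difference between siTNFR1 and siCtrl responses called 1 gene with limma, and 608 had an unadjusted p under 0.05. The called gene was SNORA80A, a small nucleolar RNA (-1.36 ± 0.19, adjusted p = 0.00218), named after its values were seen because it lies outside the naming rule, and not exact since it was undetected in untreated siCtrl cells. NFKB2 (-0.82 ± 0.25, adjusted p = 0.488), FOS (adjusted p = 0.681), NFKBIA (-0.74 ± 0.27, adjusted p = 0.67) and CXCL1 (-0.51 ± 0.26, adjusted p = 0.787) were not called. As a list, AP-1 family and immediate early genes had lower differences of response than the other genes tested, with a median of -0.27 log2. The median was -0.24 on slide 1 and -0.26 on slide 2, and camera's adjusted p was 0.00225, or 0.0116 with an estimated correlation. Of 24 members 0 were called, and 1 was lower adjusted over the list alone. Only 244 of 9586 genes were called with BV6 in siCtrl cells, so this does not set the list against other responding genes. Chemokines and cytokines also passed (adjusted p = 0.048), but not with an estimated correlation (adjusted p = 0.529). More single genes were called in the series matrix and with other background corrections, as listed in the section on processing. Slides 1 and 2 alone gave 0 calls each, the replicate block 3, the slide as a block 2, and leaving out siTNFR1 BV6 replicate 1 or 2 gave 2 each.

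With siRELA, 29 genes were called with BV6, 28 of them higher. NFKB2 was at least 4.63-fold higher, NFKBIE rose by 1.70 ± 0.16 log2, MAP3K14 by 1.47 ± 0.19, NFKBIA by 1.19 ± 0.19 and CD83 by 0.87 ± 0.14, and RNU4-2 by 3.47 ± 0.26 and RN7SK by 2.94 ± 0.26. TRAF1 was at least 1.81-fold higher. CXCL1 was undetected with and without BV6, and CXCL8 (1.10 ± 0.26, adjusted p = 0.0716) and RELB (0.81 ± 0.19, adjusted p = 0.0637) were not called. OASL, an interferon-induced gene, fell by 0.92 ± 0.18. With camera at the preset correlation, NF-kB targets were still called up with BV6 (median 0.27 log2, adjusted p = 8.38e-18). The interferon response was called down (median -0.12, adjusted p = 0.000881). Against siCtrl, 4 responses differed, all smaller: CXCL2 (-3.05 ± 0.34 log2), CXCL1 (-2.58 ± 0.26), TRAF1 (-2.50 ± 0.24) and SNORA80A (-1.57, chosen as above), with 503 genes at an unadjusted p under 0.05. These are differences of fitted values and not exact for CXCL1, undetected with siRELA, or for TRAF1 and SNORA80A, undetected in untreated siCtrl cells. NF-kB targets had 3 of 29 responses lower, or 9 adjusted over the list alone (median difference -0.54 log2, with -0.43 on slide 1 and -0.60 on slide 2; adjusted p = 0.000866 with an estimated correlation). Chemokines and cytokines had 2 of 13 lower (median -0.41, adjusted p = 0.000671 with an estimated correlation), and AP-1 family and immediate early genes 0 of 24, or 4 adjusted over the list alone (median -0.34, adjusted p = 0.000403 with an estimated correlation). As with siTNFR1, these list tests do not set a list against other responding genes. The genes higher at 9 h in the kinetic had a median BV6 change of 0.99 log2 with siCtrl and 0.52 with siRELA. The replicate block gave 8 differing responses and the slide as a block 10. Slides 1 and 2 alone gave 26 and 1 BV6 calls, and 4 and 0 differing responses.

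With siIRF1, 81 genes were called with BV6, 54 higher. TRAF1 rose by 2.83 ± 0.17 log2, NFKB2 by 1.72 ± 0.18, G0S2 by 1.71 ± 0.16, NFKBIE by 1.43 ± 0.16, RELB by 1.40 ± 0.19 and GADD45A by 1.18 ± 0.12, while RNU4-2 rose by 1.51 ± 0.26. CXCL1 was at least 1.94-fold higher and TNFAIP3 at least 2.15-fold. The mesenchymal transcription factor SNAI2 fell by 0.77 ± 0.17 and PLPP3 by 0.97 ± 0.22. BMP4, detected on only 1 untreated array, was at least 2.15-fold lower. NF-kB targets had 12 of 29 higher, or 18 adjusted over the list alone (median 0.60 log2, with 0.70 and 0.59 on the slides; adjusted p = 8.13e-05 with an estimated correlation). With the replicate number as a block, the interferon response (down, adjusted p = 0.0435), interferon-gamma and IRF1 targets (up, 0.0435), antigen presentation (up, 0.0435) and cell cycle (down, 0.0438) also passed, against 0.0653, 0.0914, 0.0793 and 0.0641 without it. The count fell to 36 without siIRF1 untreated replicate 2 or replicate 3, 49 without untreated replicate 1, 51 without BV6 replicate 1 and 47 without BV6 replicate 2, and the slides alone gave 3 and 9.

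Responses with siIRF1 and siCtrl differed in 17 genes, 16 of them smaller with siIRF1, and 435 genes had an unadjusted p under 0.05. Small nuclear and nucleolar RNAs made up 10 of them, among them RNU1-3 (-2.91 ± 0.39 log2), RN7SK (-2.78 ± 0.37), RNU4-2 (-2.70 ± 0.37) and RNVU1-18 (-2.53 ± 0.30). Among messenger RNAs, CXCL2 (-2.51 ± 0.34), CXCL1 (-1.78 ± 0.26), the histone gene H2AC17 (-1.71 ± 0.30) and GBP4 (-1.36 ± 0.24) responded less, and FOS (adjusted p = 0.323) was not called. AP-1 family and immediate early genes had 0 of 24 called, or 9 lower adjusted over the list alone (median difference -0.35 log2, with -0.24 and -0.34 on the slides; adjusted p = 0.000126 with an estimated correlation), and chemokines and cytokines 2 of 13 lower (median -0.53, adjusted p = 0.00582 with an estimated correlation). NF-kB targets had 2 of 29 lower, or 5 adjusted over the list alone (median -0.30, adjusted p = 2.44e-07, and 0.0611 with an estimated correlation). Here too the list tests do not set a list against other responding genes. The siIRF1 and siRELA differences shared 3 lower genes (0.00668 expected), with r = 0.585 across genes against 0.499 from the shared siCtrl arrays alone. Slide 2 alone gave 0 calls.

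**Figure D2:**
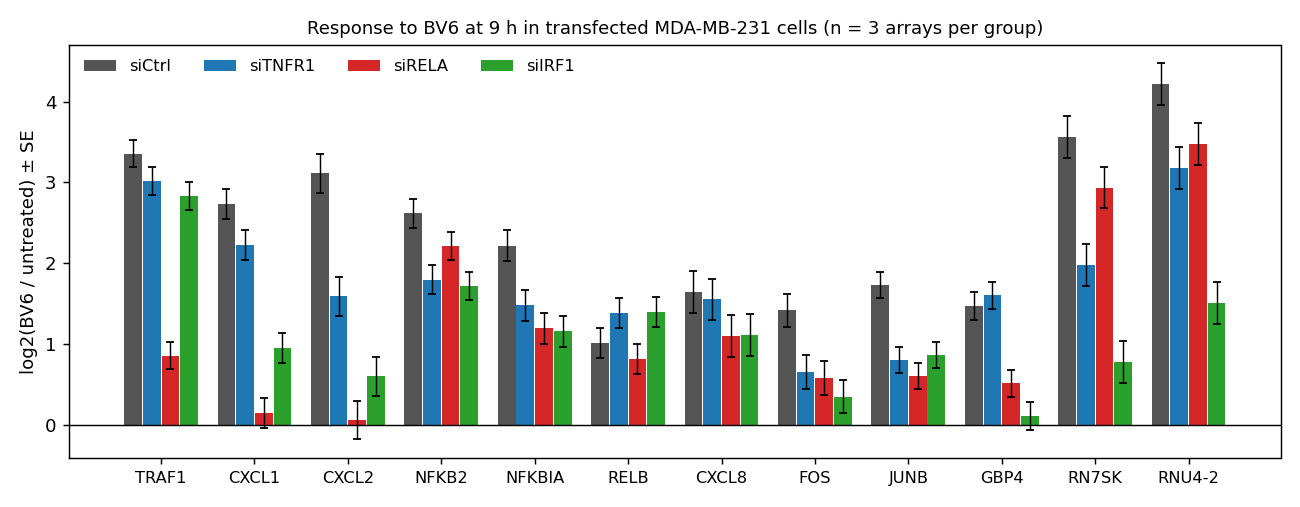
Response to BV6 at 9 h in MDA-MB-231 cells by siRNA (log2 of BV6 over untreated, vertical axis) for 12 genes (horizontal axis), as bars with 1 standard error, 3 arrays per group. NFKBIA stands at 2.22 with siCtrl and 1.19 with siRELA, and RN7SK at 3.56 and 2.94; bars of genes undetected in untreated cells, such as TRAF1 and JUNB, are fitted values given in the text as bounds, and CXCL1 with siRELA was detected on no array of either group.

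The 90 measured genes of the kinetic 9 h list had medians of 0.71 log2 with siTNFR1, 0.52 with siRELA and 0.51 with siIRF1, against 0.99 with siCtrl. The SD of the median between BV6 arrays, each set against the mean of the untreated arrays, was 0.0488 to 0.138. It leaves out the spread between untreated arrays. With the same sign as in the kinetic were 88, 88 and 82 genes, and 47, 23 and 27 were called.

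Early and late genes of the kinetic were then compared for how far each knockdown lowered their response. The 27 early genes include NFKB2, NFKBIA, RELB, MAP3K14 and GADD45A, and 13 of the 26 late genes are small nuclear or nucleolar RNAs. With siCtrl at 9 h, early genes had a median BV6 change of 0.68 log2 (13 of 27 called higher) and late genes 1.58 (23 of 26). Late genes, chosen partly by a rise at 9 h, thus had more response to lose. Differences in log2 between the classes, and their p-values, are therefore partly built in and do not show differing dependence on the siRNA targets. With siTNFR1 the median difference of response was -0.05 log2 for early and -0.92 for late genes (permutation p = 1e-05, the smallest that the permutations can give, and 2e-05 adjusted over 4 such tests). With siRELA the medians were -0.21 and -0.76 (permutation p = 3e-05), and with siIRF1 -0.11 and -1.39 (permutation p = 1e-05, again the smallest). Without the small RNAs, a comparison chosen after the data were seen, the 13 remaining late genes had medians of -0.38 with siTNFR1 (permutation p = 0.0248), -0.65 with siRELA (p = 0.0189) and -0.64 with siIRF1 (p = 0.00518). As the share of the siCtrl response that was kept, early genes kept 85.1% and late genes 51.1% with siTNFR1 (14 and 25 genes, permutation p = 0.00199), 71.7% and 19.4% with siIRF1 (p = 0.00168), and 60.4% and 57.4% with siRELA (p = 0.853). Genes are not independent replicates, so these permutations compare gene classes and not samples.

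**Figure D3:**
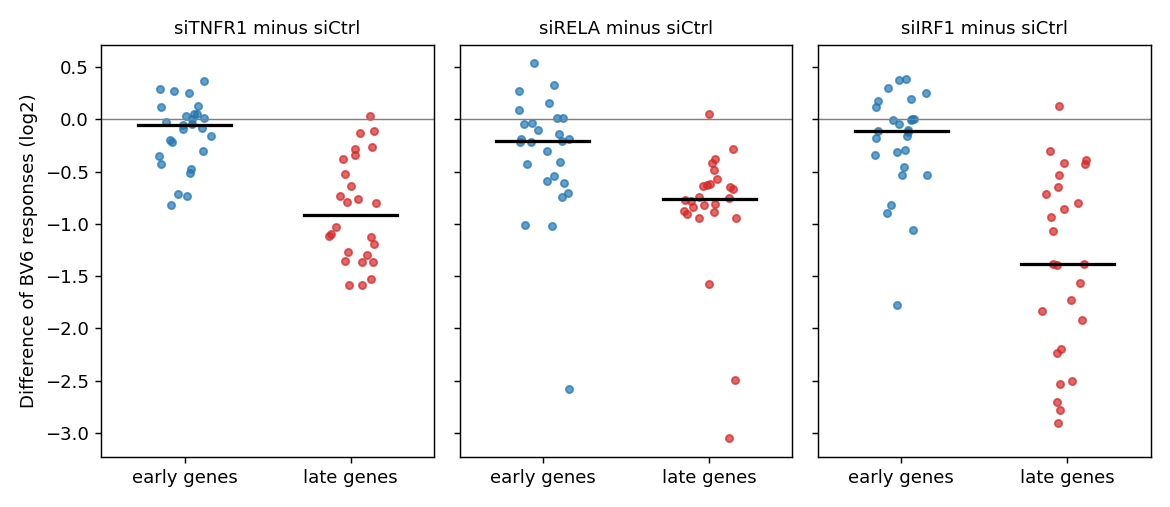
Difference of the BV6 response between each siRNA and siCtrl (log2, vertical axis) for 27 early and 26 late genes (horizontal axis), 1 point per gene, with bars at the medians. With siTNFR1 the medians are -0.05 and -0.92, with siRELA -0.21 and -0.76, and with siIRF1 -0.11 and -1.39. The median responses of the classes with siCtrl were 0.68 and 1.58, so late genes had more to lose.

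EVSA-T cells were used to ask whether the response of another line depends on TNFR1. TNFRSF1A was undetected on both siTNFR1 arrays and at least 6.62-fold lower (adjusted p = 0.0107). PGM2, at least 3.43-fold lower, and TAPT1, at least 3.32-fold higher but detected on only 1 siTNFR1 array, were the only other calls of that knockdown. BV6 gave a large response with siCtrl. Undetected on both untreated arrays, CCL20 was at least 298-fold higher, the complement gene CFB at least 132-fold, CCL2 at least 119-fold, TNF at least 77.6-fold, TNFAIP3 at least 38.4-fold, IRF1 at least 37.1-fold, and the chemokine genes CXCL10 at least 33-fold and CXCL8 at least 32.8-fold. CEBPD, an inflammatory transcription factor, rose by 5.47 ± 0.36 log2, S100A8 by 5.08 ± 0.25, NFKBIZ by 4.19 ± 0.32, NFKBIA by 3.14 ± 0.24, TAP1 by 2.95 ± 0.20 and the cell cycle inhibitor CDKN1A by 2.48 ± 0.19. SNORD3A, a U3 small nucleolar RNA, rose by 3.86 ± 0.28. TRIL, a Toll-like receptor accessory gene, fell by 2.77 ± 0.22, the iron exporter SLC40A1 by 2.35 ± 0.19 and the ribonucleotide reductase subunit RRM2 by 1.18 ± 0.23.

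In EVSA-T with siCtrl 961 genes were called, 576 higher. NF-kB targets had 28 of 29 members higher (median 2.91 log2), AP-1 family and immediate early genes 13 of 17 (median 1.24) and TNF receptor superfamily and ligand genes 7 of 11, or 8 adjusted over the list alone, each with an adjusted p = 0.0221 with an estimated correlation. All 11 measured chemokines and cytokines, of 35 listed, rose (median 3.05, adjusted p = 0.00731 with an estimated correlation). Several, such as CCL20 and CCL2, were undetected without BV6 and could pass the detection filter through their rise. The shares of list members called higher are therefore partly set by the filter. Interferon-gamma and IRF1 targets had 4 of 7 higher, antigen presentation 4 of 11, the non-canonical pathway 4 of 8 and p53 targets 4 of 12, with adjusted p-values of 0.000141, 4.48e-05, 2.08e-07 and 0.00379 that became 0.0534, 0.0718, 0.0599 and 0.0718 with an estimated correlation. One other probe of AEN, a p53 target that rose by 0.85 ± 0.22, went the other way. Cell cycle genes had 4 of 38 lower (median -0.34, adjusted p = 0.000303, and 0.224 with an estimated correlation). Interferon response genes had 2 of 9 higher and 2 lower (adjusted p = 0.737), and 0 of 17 control genes were called (adjusted p = 0.607). Leaving out siCtrl untreated replicate 1 or 2 gave 494 or 483 calls, and leaving out BV6 replicate 1 or 2 gave 627 or 538.

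With siTNFR1, EVSA-T cells had 6 calls with BV6, all higher, and 277 genes at an unadjusted p under 0.05. The count was larger with other background corrections and smaller with no detection filter, as listed in the section on processing. CCL20 was at least 51.1-fold higher, TNF at least 12.3-fold, CFB at least 7.66-fold and IGFL1 at least 3.79-fold, S100A8 rose by 2.20 ± 0.25 log2, and PPP1R15A, a stress-response phosphatase subunit, by 1.57 ± 0.23 (adjusted p = 0.0499). CCL2 (adjusted p = 0.0565) and IRF1 (adjusted p = 0.135), undetected on both untreated arrays, were not called. Chemokines and cytokines had 1 of 11 higher, or 5 adjusted over the list alone (adjusted p = 0.031 with an estimated correlation), and NF-kB targets 2 of 29, or 11 (median 0.46, adjusted p = 5.64e-27, and 0.119 with an estimated correlation). Without siTNFR1 untreated replicate 1 or 2 there was 1 call each, and without siTNFR1 BV6 replicate 2 there were 15. The knockdown's own 3 calls went to 0 without siCtrl untreated replicate 1 or 2 or siTNFR1 untreated replicate 2.

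The difference between the siTNFR1 and siCtrl responses passed in 324 genes of EVSA-T, 257 of them lower with siTNFR1, or 505 with the replicate number as a block. CCL2 responded less by -4.64 ± 0.51 log2, CXCL8 by -4.12 ± 0.26, CXCL10 by -4.01 ± 0.26, TNFAIP3 by -3.92 ± 0.51, CEBPD by -3.34 ± 0.51, IRF1 by -2.92 ± 0.58, RELB by -2.85 ± 0.28, TNF by -2.73 ± 0.56, CCL20 by -2.59 ± 0.30 and NFKB2 by -2.48 ± 0.31. SNORD3D (-3.33 ± 0.36) and RN7SK (-3.18 ± 0.40) did so too. CCL2, CXCL8, CXCL10, TNFAIP3, IRF1, RELB, TNF, CCL20 and NFKB2 were undetected in untreated siCtrl cells, and CXCL8, CXCL10 and RELB also on every siTNFR1 array, so their values are differences of fitted signals and not exact. SLC40A1 (2.70 ± 0.26) and TRIL (2.56 ± 0.31), which fell with siCtrl, had higher responses with siTNFR1. ATF3 (-0.96 ± 0.32, adjusted p = 0.16) and JUN (-1.09 ± 0.31, adjusted p = 0.095) were not called. NF-kB targets had 25 of 29 responses lower, or 28 adjusted over the list alone (median -2.48 log2), and AP-1 family and immediate early genes 4 of 17, or 10 (median -0.96), both with an adjusted p = 0.0337 with an estimated correlation. Chemokines and cytokines had 10 of 11 lower (median -2.72, adjusted p = 0.00762 with an estimated correlation). Members that passed the filter through their rise with siCtrl add to these shares. The list tests also do not set a list against other responding genes. Early and late genes of MDA-MB-231 had medians of -0.92 and -2.05 here (21 and 22 genes, permutation p = 0.0888). Their median responses with siCtrl were 0.95 and 2.66 log2, so here too late genes had more to lose. Leaving out siCtrl untreated replicate 1 or 2 gave 173 or 180 calls, siTNFR1 untreated replicate 1 gave 211 and siTNFR1 BV6 replicate 2 gave 181.

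**Figure D4:**
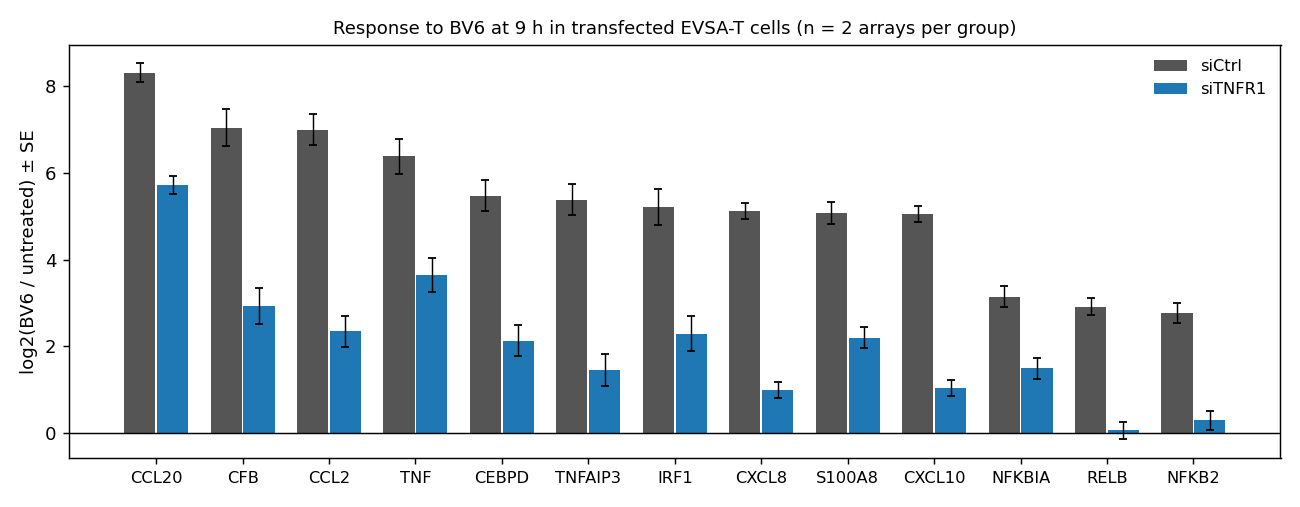
Response to BV6 at 9 h in EVSA-T cells with siCtrl or siTNFR1 (log2 of BV6 over untreated, vertical axis) for 13 genes (horizontal axis), as bars with 1 standard error, 2 arrays per group. S100A8 stands at 5.08 with siCtrl and 2.20 with siTNFR1; bars of genes undetected in untreated cells, such as CCL20, CCL2 and NFKB2, are fitted values given in the text as bounds, and CXCL8, CXCL10 and RELB with siTNFR1 were detected on no array of either group.

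The responses of the lines with siCtrl were compared directly. In EVSA-T, CCL20 (8.30 ± 0.22 log2), CCL2 (7.13 ± 0.34), TNF (5.89 ± 0.37), CXCL10 (5.03 ± 0.20), IRF1 (4.79 ± 0.49) and TNFAIP3 (4.60 ± 0.36) rose more than in MDA-MB-231, and RELB by 2.10 ± 0.30 more. TRAF1 (-3.27 ± 0.23), GBP4 (-1.44 ± 0.27) and FOS (-1.32 ± 0.27) had lower fitted responses in EVSA-T, where none of the 3 passed the detection filter, and NFKB2 (0.39 ± 0.24, adjusted p = 0.49) and CXCL1 (-0.09 ± 0.30, adjusted p = 0.931) were not called. Of these, CCL20, CCL2, TNF, CXCL10, IRF1, TNFAIP3 and RELB were undetected in untreated EVSA-T cells and TRAF1 in untreated MDA-MB-231 cells, and FOS was near background, so the values are differences of fitted signals and not exact. MAFF was called higher in EVSA-T, with another probe going the other way. The responses of 532 genes differed, 330 being higher in EVSA-T, and NF-kB targets had 21 of 38 higher and 2 lower, or 24 and 3 adjusted over the list alone (median 1.24, adjusted p = 0.0117 with an estimated correlation). Among other lists called by camera at the preset correlation, leukocyte markers (median 0.25) and mesenchymal and basal-like markers (0.15) pointed up and cell cycle genes (-0.27) down. Of genes higher in MDA-MB-231 with siCtrl, 81 were also higher in EVSA-T (8.01 expected, Fisher's exact test adjusted p = 4.49e-67), and 13 were lower in both (1.89 expected, adjusted p = 3.30e-08). Cell line, BV6 dose (5 against 50 nM) and slide differ together, so their parts cannot be told apart.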

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

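The early and late classes were measured in EVSA-T as a comparison added after the data were seen. Responses to BV6 differed between groups in 5 tested comparisons. With siCtrl, 532 genes responded differently in EVSA-T and MDA-MB-231, where dose and slide differ along with the line. In EVSA-T, 324 genes responded differently with siTNFR1 and siCtrl, and in MDA-MB-231 1 gene did, SNORA80A, which was chosen after its values were seen. With siRELA 4 genes responded differently from siCtrl and with siIRF1 17 did.

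Splits of the 12 arrays of each of these MDA-MB-231 interactions exchanged siRNA labels within each treatment, 100 splits each with the real one included. As many calls as the real 1 gene of siTNFR1 came from 25 splits, with up to 225 calls in another split. For siRELA 17 splits gave 4 calls or more, up to 1268, and for siIRF1 14 splits gave 17 or more, up to 1249. Splits that call so many genes point to a structure of the samples, since uneven exchanges carry the knockdowns' own differences into one treatment. These splits are therefore no measure of chance, and whether chance can be excluded for the 3 counts is left undecided.

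In EVSA-T cells given siTNFR1, part of the BV6 response was left, with CCL20 at least 51.1-fold and TNF at least 12.3-fold higher. One candidate explanation is TNFR1 protein left after the knockdown. The test assumed that this would leave the early and late classes the same share of their response, which need not hold. Early genes kept 10.7% and late genes 23.3%, a difference of -12.7 points (15 and 20 genes, permutation p = 0.107). Because of that assumption the shares cannot decide on the explanation, which stays open. A response that does not need TNFR1 is open too, since TNFRSF1A was undetected with siTNFR1 and its fold is known only as a bound.

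Probes without a gene symbol took no part in the comparisons of the report. Fitted by themselves with limma, 34 of 3188 were called with BV6 in siCtrl MDA-MB-231 cells, 27 of them higher. At 15 h of the kinetic 115 of 3365 were called, 86 higher, against 0 between untreated cells of 15 h and 0 h, with 100 at an unadjusted p under 0.05. In EVSA-T with siCtrl 243 of 2468 were called, 197 higher, against 0 with siTNFR1, where 83 had an unadjusted p under 0.05.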

How the results depend on the processing

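Over 37 main results, 450 alternative values were computed. Of these, 318 stayed within 1.5 times or the spread between BV6 replicates, or kept direction and call. Another 130 moved, 2 lost their call and 0 reversed. Of 15209 alternative values of 791 named gene calls, 13225 kept direction and call, 1983 kept direction only and 1 reversed: CCN2 with BV6 in siCtrl cells went to 0.062 log2 on slide 2 alone. Of 240 alternative values of 120 list calls, 154 kept and 86 lost theirs. The normexp correction, the early and late classes in EVSA-T and the classes without small RNAs were chosen after the data were seen. Counts below are calls; except where fewer arrays, other controls, more probes tested or a stricter demand is the alternative itself, the cause was not tested. Dim genes near background limit what small changes can show.

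With no detection filter, which tests more probes, there were 2 for the siTNFR1 interaction in MDA-MB-231, 22 at 3 h, 31 at 6 h, 1 for BV6 with siTNFR1 in EVSA-T and 0 for the EVSA-T knockdown. In the same order except 6 h, the series matrix gave 10, 69, 15 and 7, no background correction 10, 68, 13 and 7, normexp 6, 66, 14 and 7, and limma's trend and robust options 2, 63, 12 and 7, and each of these 4 gave 1 for untreated 15 h against 0 h. Medians of the kinetic 9 h genes in the series matrix were 0.69, 0.53, 0.36 and 0.37 for higher genes with siCtrl, siTNFR1, siRELA and siIRF1, and -0.33 and -0.30 for lower genes with siCtrl and siTNFR1. With the list taken against untreated 9 h only they were 1.46, 0.89 and 0.72 with siCtrl, siTNFR1 and siRELA, and for lower genes -0.67, -0.62, -0.35 and -0.61 in the order of the 4 siRNAs.

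The replicate number as a block gave 389 for BV6 with siCtrl, 192 with siTNFR1, 3 and 8 for the siTNFR1 and siRELA interactions, 509 for the siTNFR1 knockdown, 87, 94, 219, 673 and 1112 at the 5 kinetic times, and 10, 505 and 7 for BV6 with siTNFR1, the interaction and the knockdown in EVSA-T. It changed none of the 791 gene calls. The slide as a block gave 2 and 10 for the siTNFR1 and siRELA interactions and 487 for the siTNFR1 knockdown. Demanding a 1.5-fold change left 1220 for siRELA and 1268 for siIRF1 knockdown. With only the groups of a comparison in the fit there were 133, 69, 15 and 38 for BV6 with siCtrl, siTNFR1, siRELA and siIRF1, 179 for the siTNFR1 knockdown, 22 at 3 h, and 1 and 0 for BV6 with siTNFR1 and the knockdown in EVSA-T.

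Slide 1 alone gave 123, 16 and 3 for BV6 with siCtrl, siTNFR1 and siIRF1, 0 for the siTNFR1 interaction, and 47, 1132 and 790 for the siTNFR1, siRELA and siIRF1 knockdowns. Slide 2 alone gave 30, 45, 1 and 9 for BV6 with siCtrl, siTNFR1, siRELA and siIRF1, 0 for each of the 3 interactions with limma, and 102, 536 and 785 for the knockdowns. Slide 3 alone gave 22, 12, 69, 215 and 209 at the kinetic times, untreated 0 h as the only control 20, 21, 54, 241 and 398, and untreated cells of the same time 54 at 9 h and 397 at 15 h. As the share of response kept, early and late genes under siRELA differed by 2.96 points (permutation p = 0.853), and in EVSA-T the classes differed by 1.13 log2 with siTNFR1 (permutation p = 0.0888). List calls went from 120 to 57 with an estimated correlation and to 216 with fry's mixed test, which asks for change in either direction.

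Without 1 replicate at a time, where a lone remaining array is assumed to vary like the other groups, counts ran from 132 to 233 for BV6 with siCtrl, 82 to 105 with siTNFR1, 36 to 54 with siIRF1, 1 to 2 for the siTNFR1 interaction and 193 to 315 for the siTNFR1 knockdown. In the kinetic they ran from 15 to 390 at 3 h, 9 to 56 at 6 h, 30 to 116 at 9 h, 117 to 385 at 12 h and 238 to 719 at 15 h. In EVSA-T they ran from 483 to 627 for BV6 with siCtrl, 1 to 15 with siTNFR1, 173 to 256 for the interaction and 0 to 2 for the knockdown.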

Other observations

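The tests of the slide, of shared probes and of the share kept with siIRF1 were chosen, or given their present bounds, only after their results were seen. The bound for background correction was changed after the normalized median was known but before the unprocessed one was. Small nuclear and nucleolar RNAs were called higher in growing numbers over the kinetic. Of 104 measured, 0 were called higher at 3 h with limma, 2 at 6 h, 20 at 9 h, 52 at 12 h and 58 at 15 h, when their median was 0.75 log2. They include spliceosomal RNAs such as RNU4-2 (5.83 ± 0.33 at 15 h), the U3 nucleolar RNA SNORD3D (4.08 ± 0.25) and RN7SK (3.69 ± 0.17). Histone genes, whose messages mostly end without a poly(A) tail, rose as well, with 27 of 33 called higher at 15 h (median 1.81 log2), among them H4C8 (3.83 ± 0.26). In siCtrl cells 22 of 82 small RNAs were called higher, against 7 with siTNFR1, 10 with siRELA and 2 with siIRF1, and by the test of the difference from siCtrl 10 responses were smaller with siIRF1, 1 with siTNFR1 and 1 with siRELA. In EVSA-T 36 of 75 were called with siCtrl and 0 with siTNFR1, and 23 responses were smaller with siTNFR1. Untreated cells at 15 h against 0 h had 0 calls (median -0.02).

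The genes that siTNFR1 changed in untreated MDA-MB-231 cells leaned the same way in EVSA-T. Leaving TNFRSF1A aside, 221 of 261 measured genes had the same sign in both lines, 84.7% against 56.8% of other genes. Their median was 0.32 log2 in EVSA-T (permutation p = 1e-04, the smallest that the permutations can give). The permutations compare genes, which are not independent replicates. The fall of PGM2 and the rise of TAPT1 were called in both lines. EVSA-T was compared with siCtrl as well, and 165 of the 317 genes called in MDA-MB-231, TAPT1 among them, changed the same way with all 3 siRNAs. For these, siCtrl cells lay away from untransfected ones, with a median signed difference of -0.777 log2 on the arrays used to choose the genes. On the BV6 arrays, which were not so used, it was -0.611. An effect of the control siRNA could therefore give the same agreement.

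For the rise of small RNAs, 5 explanations were tested. The slide is argued against by EVSA-T, whose arrays lie on 1 slide, since with siCtrl the lowest BV6 array median of the class exceeded the highest untreated one by 1.29 log2; a first bound, a class median above 1 there, was not reached (0.73). For probes shared between near-identical copies, 12 families of small RNAs had a called member at 15 h. This argues against copies of 1 RNA as the source of the whole rise. Some families may be alike in sequence, which was not tested. Within a family, shared probes may still add to the number of calls, so there this explanation stays open. Open are background correction and normalization, as the unprocessed median at 15 h was 0.361 log2 (all genes -0.22) against 0.754 after normalization. With siIRF1, 10 of 82 measured class members responded less than with siCtrl, so part of their rise was lost. Open too is whether the class lost a larger share than other responding genes. The 24 class members that rose at least 1.5-fold with siCtrl were compared with 196 other genes that did. These sets were not matched on the size of the rise. With siIRF1 the class differed by -20.3 points in the share kept (24 and 196 genes, permutation p = 0.0511). With siTNFR1 the class kept 41.2% against 60.4% (permutation p = 0.0760), and with siRELA 56.8% against 32.1% (permutation p = 0.00651). More RNA without a poly(A) tail being labelled in BV6 samples could also give the rise, as 94.2% of members lay above 0 at 15 h, so the rise may be of technical origin.

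Of the genes changed by siTNFR1, siRELA and siIRF1 in untreated cells, 165 changed the same way in all 3 (3.45 expected if independent), 139 higher and 26 lower. Chance values of the untreated siCtrl arrays are argued against by the BV6 arrays, which took no part in choosing these genes and gave a median signed change of 0.769 log2, against 0.826 on the untreated ones. Untreated siCtrl cells lay on the other side of untransfected cells, with a median signed difference of -0.777 log2 (-0.81 for the higher and -0.34 for the lower genes). The choice of genes used these same siCtrl arrays, which pushes the difference to that side. On the BV6 arrays, which were not so used, it was -0.611 (-0.656 for the higher and -0.178 for the lower genes). The mean of the other siRNAs in untreated cells differed from untransfected cells by 0.047 for the higher and 0.47 for the lower genes. A candidate explanation, which stays open for the lower genes, is an effect of the control siRNA itself. The untransfected cells came from another experiment and other slides, and no biological explanation was tested.

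Other splits of 6 arrays into 3 and 3 number 10 with the real one, too few for a share under 0.05, and in each comparison 1 split, the real one, gave as many calls. For BV6 the real counts were 244 with siCtrl, 127 with siTNFR1, 29 with siRELA and 81 with siIRF1, and the highest others 0, 1, 1 and 0. For the knockdowns the real counts were 317 with siTNFR1, 2012 with siRELA and 2087 with siIRF1, and the highest other was 0 in each. Every other split mixes arrays of both real groups, so real differences widen the spread and partly cancel in the means. The low counts of the other splits are therefore no measure of chance.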
